A study of Mus musculus with 4 samples.

How the data were processed

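The data were 4 single-cell RNA libraries of mouse aorta, 1 each from P5, P10, P20 and P30, prepared with 10x Genomics 3′ chemistry version 3.1 and sequenced on a NextSeq2000. Per the labels, aortas of several animals were pooled, their adventitia was removed and vessels were perfused with a calcium chelator. Cells passed a strainer before loading. The labels did not state how many animals were pooled, their sex or their strain. The matrices deposited by the authors hold raw UMI counts for 32285 genes, called to cell barcodes with Cell Ranger 7.1.0 (per the file headers) on mm10. Their later steps in Seurat 5.1.0 left no values in these matrices. Every barcode had at least 500 UMIs. Entries sharing a symbol were kept apart and the first one stood for the symbol. Gene positions came from GENCODE release 21 for mouse build 38, matched by Ensembl identifier for 32129 of the 32245 entries left with 1 per symbol.

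Samples, comparisons, gene lists, cell type markers, the rule for named genes and most alternatives were fixed before the data were examined. Barcodes were kept with at least 1000 UMIs and 500 genes and at most 10% mitochondrial UMIs, which left 30657 barcodes (92.4%) at P5, 20569 (90.6%) at P10, 10365 (69.0%) at P20 and 17603 (90.8%) at P30. Scrublet, run in scanpy 1.11.5 with an expected doublet rate of 0.1, scored each library. The score threshold of 0.25 was set after the automatic one had called 13 doublets at P20 and 1 at P30. It removed 4403 barcodes (14.4%) at P5, 2458 (12.0%) at P10, 885 (8.54%) at P20 and 2137 (12.1%) at P30. Each library was then clustered alone on 2000 variable genes, 30 principal components and 20 neighbours with the Leiden method (igraph 0.11.9) at resolution 1, in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and anndata 0.12.19. Figures were drawn with matplotlib 3.10.9.

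Clusters were named from 18 marker lists, for endothelial, lymphatic endothelial, smooth muscle, pericyte, fibroblast, macrophage, lymphocyte, neutrophil, mast, erythroid, Schwann, neuronal or chromaffin, mesothelial, adipocyte, chondrocyte, skeletal muscle, cardiomyocyte and epithelial cells. The pericyte list was barred from naming a cluster, because smooth muscle cells carry its markers too. A marker entered the score of its class if it reached 50 CPM or more in any but the smallest clusters. It counted as detected in a cluster when at least 10% of the cluster's cells held it. A class was given when its score was at least 0.2 and at least 1.4 times that of the next class, with at least 3 detected markers. A cluster whose 10 leading genes held more markers of another class stayed unnamed. These thresholds were set after the clusters had been seen. Clusters of 1 class were pooled within a library and called by the class name with "-like".

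The cycling share was the share of cells with at least 3 UMIs over the 22 mitosis genes after each cell was thinned at random to 2000 UMIs, shallower cells being left out. These are genes of G2 and M phase, so the share counts cycling cells and not only cells in mitosis. Shares have exact (Clopper-Pearson) 95% binomial intervals, and a share of 0 is given with the limit that 3 counts allow. For expression, UMIs were summed over the cells of a class in a library and scaled to CPM, with all UMIs of the class as the total. Steps are log2 ratios of these values with the exact conditional 95% interval of a ratio of 2 Poisson counts. Cells are not replicates, so no p-value, SE or count of differing genes was computed. Classes were compared where both libraries held at least 50 cells. Fibroblast-like cells were used beside the other classes only.

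The 31 gene lists covered cell division (S phase, mitosis, cell cycle arrest), metabolism (fatty acid uptake and handling, fatty acid oxidation, fatty acid synthesis, sterol synthesis, glycolysis, oxidative phosphorylation), endothelial identity and signalling (flow response, arterial and Notch, venous and capillary, angiogenic front, junctions, BMP and TGF-beta, YAP and TEAD targets, mesenchymal transition, apoptosis and extrusion, Hox), matrix and growth (elastic and fibrillar matrix, basement membrane, contractile, imprinted growth genes, IGF axis, ribosome biogenesis) and state (dissociation stress, interferon response, antigen presentation, inflammatory adhesion, circadian clock, glucocorticoid response). A member was measured with at least 20 UMIs over both libraries of a step. Each list's median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list stood apart when it lay outside their central 95%. Members at least 1.5-fold higher or lower were counted.

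Named genes were the 12 highest and 12 lowest log2 ratios in endothelial-like cells for P10 against P5 and P30 against P20, the 6 highest and 6 lowest for P20 against P10 and P30 against P5, and the 8 highest and 8 lowest in smooth muscle-like cells. Trend genes were the 10 largest rises and 10 largest falls from P5 to P30 among genes that differed at least 1.2-fold in the same direction at each step. A gene was eligible with at least 200 UMIs over both libraries, at least 50 CPM in the higher one and, there, at least 0.5 of its highest level in any other named class. That left 3179 genes for P10 against P5, 2814 for P30 against P20, 3074 for P20 against P10, 3296 for P30 against P5 and 3060 in smooth muscle-like cells. Mitochondrial, ribosomal protein, hemoglobin, immunoglobulin, sex-linked marker, predicted and stress-list genes were left out. Within lists, members with the largest ratios were named, and 15 genes chosen beforehand, such as Klf2, Eln and Fabp4, were always allowed. Gm42418, Xist, Ddx3y, Fos, Dbp, Hlf, Tagln, Cnn1, Nkx2-3, Gkn3 and the leading genes of clusters were added after their values were seen.

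Alternatives were a stricter filter (2000 UMIs, 1000 genes, 5% mitochondrial), a looser filter (500 UMIs, 200 genes, 20%), doublets kept, resolution 0.5, the 4 libraries clustered together without batch correction, TMM factors (edgeR 4.0.16 in R 4.3.3), the mean over cells of CPM, cells with a UMI of other classes' markers left out, cells with at least 2 mitosis UMIs left out, and no filter on low counts. For the cycling share they were thinning to 1000 UMIs and a minimum of 2 UMIs. Alternatives chosen after seeing the data were CPM without hemoglobin and mitochondrial UMIs, capillary-like clusters left out (at least 3 of Fabp4, Gpihbp1, Cd36 and Plvap at 4 times or more the library's endothelial-like level), unnamed clusters with smooth muscle as best class added, Xist-only and Y-only cells, and subtraction of smooth muscle RNA at P5 and P10. The subtracted share was the median, over 14 smooth muscle genes outside all lists, of the endothelial-like over the smooth muscle-like level. TMM factors and CPM without hemoglobin and mitochondrial UMIs shift all ratios of a step by the same amount. A list's place among random lists can then change only through the expression bins, so calls kept under them add no support. Leaving out mitotic cells selects cells by unthinned UMIs of the mitosis list, which itself shapes the mitosis median.

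The method was tested on simulated data drawn from the endothelial-like and smooth muscle-like sums. True folds of 1.5 and 2 came back as medians of 1.49 and 2.01 at P10 against P5 and 1.49 and 1.98 at P30 against P20, in the right direction for 100% of the changed genes. Of 1000 simulated lists without a difference 3.9% stood apart at P10 against P5, 3.8% at P30 against P20 and 4.0% in smooth muscle-like cells, and of 40 lists with changed members 100% did. Both simulated libraries came from 1 shared profile, and the lists without a difference held genes picked at random. These rates cover counting error only. They give no rate of false calls for lists of genes that vary together or for shifts of a whole library.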

Results

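Mouse aorta was profiled by droplet-based single-cell RNA sequencing at postnatal day 5 (P5), P10, P20 and P30, with 1 library of pooled aortas at each age. The series concerns how arteries grow and keep their proportions after birth, and the comparisons follow the endothelium over 4 ages and the smooth muscle over the younger ages. At P5 and P10 the whole aorta, stripped of adventitia, was digested with Liberase TH for 20 min. At P20 and P30 the endothelium was scraped off with a blade and treated with trypsin for 5 min and again for 5 min. P10 against P5 and P30 against P20 therefore compare libraries made the same way, and in P20 against P10 and P30 against P5 age and dissociation cannot be told apart. The P5 library held 157882131 unique molecular identifiers (UMIs) over 33180 barcodes, the P10 library 118479025 over 22710, the P20 library 81692394 over 15014 and the P30 library 107311183 over 19383. Median UMIs per barcode were 3699 at P5, 4427.5 at P10, 4202 at P20 and 4482 at P30. No age had a replicate library, so no difference between ages was tested. The 95% intervals of shares of cells, levels and log2 ratios cover counting error only.

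Smooth muscle-like cells made up most of the digested aortas and endothelial-like cells most of the scraped ones. Endothelial-like cells, named from genes such as Pecam1 and Cdh5, were 9.39% of the kept cells at P5 (95% interval 9.04 to 9.75, 2466 cells) and 8.53% at P10 (8.13 to 8.95, 1545 cells). After scraping they were 72.6% at P20 (71.7 to 73.5, 6883 cells) and 79.2% at P30 (78.5 to 79.8, 12243 cells). Smooth muscle-like cells, named from contractile genes such as Myh11, were 69.3% (68.7 to 69.9) at P5 and 61.9% (61.1 to 62.6) at P10. At P20 they were 0.148%, or 14 cells, and at P30 none of 15466 cells was named so, which allows a share of up to 0.0194%. Fibroblast-like cells, marked by Pdgfra and Dcn, were 14.9% at P5, 25.8% at P10, 9.72% at P20 and 13.8% at P30, with 9.48% at P5 when clustering was coarser. Macrophage-like cells numbered 212, 310, 274 and 398 from the youngest to the oldest library. Lymphatic endothelial-like cells numbered 65 at P10, 159 at P20 and 174 at P30, and lymphocyte-like cells 418 at P20 and 328 at P30. The remaining named cells were 400 erythroid-like at P20 and 24 at P30, 46 Schwann-like at P5 and 43 at P10, 16 mast-like at P10 and 25 neutrophil-like at P20. The counts of small classes moved with the processing: the stricter filter left 71 lymphocyte-like cells at P30, and the looser filter named 2084 erythroid-like cells at P20. Under the main settings no cluster was named neuronal or chromaffin, mesothelial, adipocyte, chondrocyte, skeletal muscle, cardiomyocyte or epithelial, and the looser filter named 21 cells at P20 mesothelial. Pericytes could not be named under any setting, so their presence was not assessed.

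Some clusters stayed without a name under naming thresholds that were set after the clusters had been seen. At P5 these held 1433 cells, 1294 of them in 1 cluster led by Erbb4 and Rgs5 whose best-scoring class was smooth muscle. Rgs5 was also on the pericyte list, which was not used for naming. At P20 they held 386 cells, 301 of them in a shallow cluster led by the hemoglobin genes Hba-a1 and Hbb-bs whose best-scoring class was endothelial. Of the named endothelial-like clusters, 1 at P20 with 40 cells was led by the cytotoxic lymphocyte genes Gzma and Ccl5. These genes are not on the lymphocyte marker list, so they did not count against its name. Hemoglobin genes took 0.0258% of all UMIs at P5, 0.496% at P10, 12.4% at P20 and 0.775% at P30, and within endothelial-like cells 0.00805%, 0.166%, 0.914% and 0.316%.

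Endothelial-like cells expressing mitosis-list genes, counted as cycling, were most frequent at P5. The share with at least 3 UMIs over 22 mitosis genes, after every cell was thinned to 2000 UMIs, was 13.3% (11.9 to 14.8, 290 of 2179 cells) at P5 and 4.11% (3.13 to 5.28, 58 of 1412) at P10. In the scraped libraries it was 6.14% (5.54 to 6.78, 364 of 5926) at P20 and 2.80% (2.501 to 3.12, 315 of 11257) at P30. Mki67, the proliferation marker, had a UMI in 12.2%, 3.05%, 4.91% and 2.53% of these cells from P5 to P30, and Top2a, a topoisomerase of dividing cells, in 14.8%, 5.24%, 5.80% and 2.94%. Smooth muscle-like cells showed 17.7% (17.1 to 18.2) at P5 and 6.57% (6.08 to 7.08) at P10. Fibroblast-like cells had 11.3% at P5, 0.422% at P10, 5.50% at P20 and 0.360% at P30, so the P10 and P30 fibroblast-like cells served as the low reference. Their median depths were 4826 and 5544 UMIs, against 4209 and 4616 in endothelial-like cells of those libraries. Without thinning, the endothelial-like shares were 23.1%, 8.35%, 9.92% and 4.12%. A looser cell filter lowered the endothelial-like share at P5 to 6.96%, and keeping predicted doublets gave 8.43% at P5, 1.89% at P10 and 2.70% at P30, so that P10 was then the lowest. In fibroblast-like cells, keeping doublets gave 3.67% at P5, and clustering the libraries together gave 1.84% at P10 and 0.777% at P30.

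**Figure D1:**
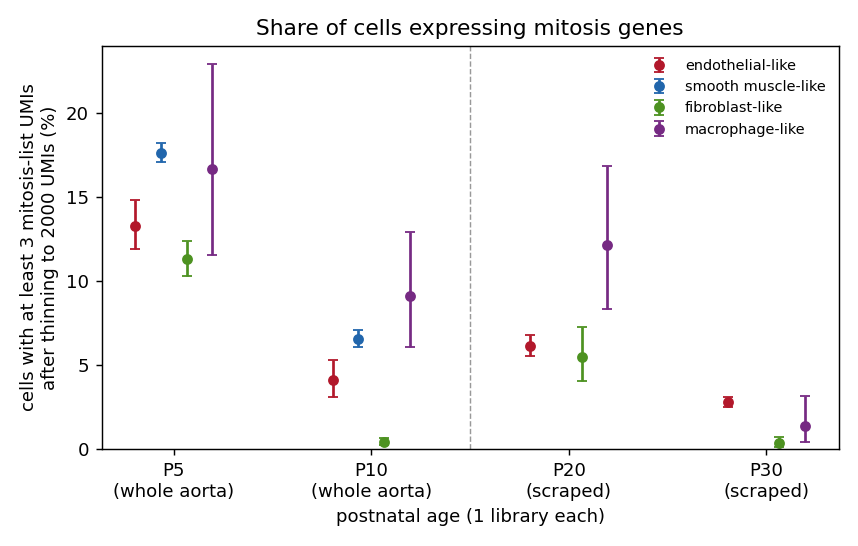
Share of cells (percent, vertical axis) with at least 3 UMIs over 22 mitosis genes after thinning to 2000 UMIs, by age (horizontal axis) and cell class, with exact 95% binomial intervals; the dashed line separates the 2 dissociations. Endothelial-like cells stood at 13.3% at P5, 4.11% at P10, 6.14% at P20 and 2.80% at P30.

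From P5 to P10, endothelial-like cells carried fewer transcripts of dividing cells and more of antigen presentation and of a retinoid-metabolising enzyme. All 22 measured mitosis genes were at least 1.5-fold lower at P10, with a median log2 ratio of -1.33. Mki67 (ENSMUSG00000031004, mouse build 38 chromosome 7, 135689784 to 135716361) stood at 119 CPM (UMI counts scaled to the total of the class) at P5 and 37.3 at P10, which was 3.19-fold lower (log2 -1.67, 95% interval -1.85 to -1.499). Adh7 (ENSMUSG00000055301, chromosome 3, 138217760 to 138233382), an alcohol dehydrogenase that oxidises retinol, was 18.6 CPM at P5 and 78.2 at P10, or 4.21-fold higher (log2 2.07, 1.86 to 2.29). The MHC class I gene H2-K1 was 206 CPM at P5 and 689 at P10 (log2 1.74, 1.67 to 1.81).

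The other genes with the lowest ratios at this step were mostly cell-cycle genes. They were Ube2c (log2 -1.505), Nusap1 (-1.501), Cenpf (-1.47), Top2a (-1.44) and Cdk1 (-1.39), which act in mitosis, Cks2 (-1.30), which binds Cdk1, and Hmgb2 (-1.46), a chromatin protein. The rest were Sparcl1 (-1.38), a secreted matricellular protein, Rp1 (-1.35), Dync1i1 (-1.30), a dynein chain, and the mRNA export factor Alyref (-1.29). Among 20 S phase genes, 13 were at least 1.5-fold lower (median -0.73), led by Clspn (25.0 to 9.31 CPM) and Uhrf1 (20.0 to 8.03 CPM). With the looser cell filter, which left 2043 in place of 2466 endothelial-like cells at P5, the mitosis median was -0.14 and the S phase median -0.49. Under that filter Mki67 was at -0.52, Top2a at -0.24 and Ube2c at -0.12, and the other cell-cycle genes and Hmgb2 lay between -0.10 (Nusap1) and -0.72 (Hmgb2).

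Higher at P10 beside Adh7 and H2-K1 were H2-Q7 (log2 2.05), a class I gene whose reads are shared with close paralogs, Slco1c1 (1.79), a thyroid hormone transporter, and Adra2a (1.70), the alpha-2A adrenergic receptor. Klf9 (1.60), a hormone-induced transcription factor, Muc13 (1.54), a membrane mucin, Frmd5 (1.53) and Gadd45b (1.35), a stress-induced gene, followed. Cmss1 (1.68), Camk1d (1.46) and AY036118 (1.48) were higher in smooth muscle-like (1.496, 1.48 and 1.03) and fibroblast-like cells (1.54, 1.69 and 0.90) too. AY036118 lies wholly within Gm42418, a locus with ribosomal RNA sequence, on the opposite strand (923 of 923 bases, chromosome 17), so its level is uncertain. Gm42418 itself was 4662 CPM at P5, 13077 at P10, 30234 at P20 and 20815 at P30 in endothelial-like cells.

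Of the 31 gene lists, 6 lay above and 10 below the central 95% of random lists matched on expression. Antigen presentation had the largest positive median, 0.99, with 9 of 15 members at least 1.5-fold higher and none lower. Its class II members H2-Aa (0.797 to 8.73 CPM) and Cd74 (1.36 to 12.8 CPM) were scarce at P5. Cd74 was at similar levels in smooth muscle-like cells (1.51 to 15.5 CPM), and macrophage-like cells made up 0.807% and 1.71% of the kept cells, so the part of the class II ratios that belongs to endothelial-like cells was not measured. Circadian clock genes had a median of 0.60 with 8 of 14 higher, such as Dbp (9.01 to 23.2 CPM). The interferon response list stood at 0.44 with 6 of 15 higher, Ly6a going from 11.3 to 34.6 CPM, and inflammatory adhesion at 0.34 with 4 of 12 higher and 1 lower, Vcam1 going from 52.7 to 106 CPM. Glycolysis stood at 0.24 with 3 of 15 higher, among them Pfkfb3 (25.4 to 48.5 CPM), and BMP and TGF-beta at 0.21 with 5 of 18 higher and 1 lower, Atoh8 going from 7.33 to 18.4 CPM.

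Below the random lists, elastic and fibrillar matrix had a median of -0.37 with 6 of 22 members lower and 2 higher. Tnc went from 55.4 to 14.9 CPM and Mfap2 from 221 to 107 CPM, while Eln, the elastin gene, was 54715 CPM at P5 and 44128 at P10 and Col1a1 956 and 971. The angiogenic front list stood at -0.33 with 3 of 10 lower and 2 higher, Igfbp3 going from 37.1 to 11.4 CPM. Sterol synthesis was at -0.28 with 2 of 19 lower and the contractile list at -0.25 with 3 of 16 lower. The contractile median was 0.12 with the looser filter, 0.14 with doublets kept and 0.89 after subtraction of smooth muscle RNA. Dissociation stress stood at -0.24 with 4 of 20 lower and 5 higher, Fos going from 2546 to 1767 CPM and Hspa1a from 17.4 to 45.5 CPM. Imprinted growth genes stood at -0.20 with 4 of 18 lower and 1 higher, the lower ones including H19 (33.6 to 11.6 CPM) and Dlk1 (9.96 to 1.86 CPM), while Igf2 was 117 and 121 CPM. Ribosome biogenesis was at -0.15, and at 0.13 in cells with Xist and no Y-linked UMIs, and oxidative phosphorylation at -0.14, with none of the 28 members of the latter past 1.5-fold. Smooth muscle RNA in endothelial-like cells was also lower at P10. Over 14 smooth muscle genes outside all lists, the endothelial-like level was 16.0% of the smooth muscle-like level at P5 and 7.19% at P10. Free RNA of fibroblast-like cells, where H19 was 153 and 125 CPM, was not subtracted.

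The other 15 lists lay within the range of random lists. Their medians were -0.16 for the IGF axis, -0.14 for basement membrane, -0.11 for arterial and Notch, -0.04 for fatty acid uptake and handling, -0.02 for junctions, 0.01 for fatty acid synthesis, 0.03 for flow response and for fatty acid oxidation, and 0.04 for mesenchymal transition. Apoptosis and extrusion stood at 0.08, cell cycle arrest at 0.09, venous and capillary at 0.10, Hox at 0.14, YAP and TEAD targets at 0.16 and glucocorticoid response at 0.18. Within the flow response list, the shear-induced factors Klf2 (1777 to 958 CPM) and Klf4 (621 to 392 CPM) were lower at P10. The dissociation stress median was lower at this step too (-0.24), and whether flow or tissue handling lay behind Klf2 and Klf4 was not tested. The lipid handling genes Fabp4 (425 and 454 CPM), Cd36 (13.3 and 17.9 CPM) and Gpihbp1 (13.0 and 9.54 CPM) differed by less than 1.5-fold over the class. Much of this signal lay in capillary-like clusters of 60 cells at P5 and 44 at P10, with Gpihbp1 at 548 and 402 CPM there and at most 1.13 CPM in the other clusters. In the largest endothelial-like cluster Fabp4 was 200 CPM at P5 and 74.2 at P10, and in the next largest 334 and 1033. The junction genes Cdh5 (396 and 294 CPM) and Pecam1 (1405 and 1649 CPM) differed by less than 1.5-fold.

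The sex mixture of the animals differed between these libraries. Xist was 446 CPM at P5 and 25.7 at P10 in endothelial-like cells, and Ddx3y, on the Y chromosome, 10.7 and 75.9 CPM. In cells with Y-linked and no Xist UMIs at both ages, the interferon response median was -0.25, dissociation stress 0.00036 and antigen presentation 0.51, and Slco1c1 was at 2.98 and Adra2a at 3.46. In cells with Xist and no Y-linked UMIs, of which P10 had 66 and whose sex is less certain at that age, the interferon response median was 0.90 and dissociation stress -0.96, and Slco1c1 was at -0.15, Adra2a at 0.79, Muc13 at 0.16, Sparcl1 at -0.23 and Rp1 at -0.65. Of the 16 lists that stood apart, 5 did so under each of 14 alternatives, with the range of medians over the alternatives in brackets. These were S phase (-1.19 to -0.49), mitosis (-1.51 to -0.14), glycolysis (0.19 to 0.29), matrix (-0.45 to -0.29) and antigen presentation (0.51 to 1.38). Imprinted growth genes (-0.29 to -0.17), dissociation stress (-0.96 to 0.00036) and circadian clock (0.26 to 0.70) stood apart under 13 and oxidative phosphorylation (-0.19 to -0.13) under 12. Inflammatory adhesion (0.19 to 0.51) and BMP and TGF-beta (0.0081 to 0.31) did so under 10, angiogenic front (-0.69 to -0.02) under 9 and interferon response (-0.25 to 0.90) under 8. Sterol synthesis (-0.30 to -0.02) did so under 7, contractile (-0.27 to 0.89) under 6 and ribosome biogenesis (-0.24 to 0.13) under 4.

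From P20 to P30, endothelial-like cells of the scraped libraries again had fewer mitotic transcripts and more class I MHC transcripts, together with more immediate early gene transcripts and clock genes that differed in both directions. Of 22 mitosis genes, 18 were at least 1.5-fold lower (median -0.88), Mki67 going from 63.6 to 29.6 CPM (log2 -1.10). H2-K1 (ENSMUSG00000061232, chromosome 17, 33996017 to 34000347) went from 702 to 1687 CPM (log2 1.27, 1.25 to 1.28) and its light chain B2m from 303 to 669 CPM (1.14, 1.12 to 1.17). Adh7 was 244 CPM at P20 and 614 at P30 (1.33, 1.30 to 1.36). The basement membrane collagen gene Col4a5 (ENSMUSG00000031274, chromosome X) was 4.79-fold lower at P30, at 83.6 and 17.5 CPM (log2 -2.26, -2.35 to -2.17).

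Higher at P30 were further class I genes, H2-Q6 (2.80), H2-Q7 (2.18) and H2-Q4 (1.25), which share reads with each other. Cirbp (1.74), a cold-induced RNA-binding protein, Nfkbiz (1.49), a regulator of NF-kB targets, and Adh1 (1.403), another retinol dehydrogenase, stood with them. So did Clu (1.26), a secreted chaperone, Parm1 (1.18) and Iigp1 (1.11), an interferon-induced GTPase. Lower at P30 were the clock gene Per3 (-1.76), the endoplasmic reticulum stress proteins Manf (-1.402), Hspa5 (-1.34) and Creld2 (-1.08), and the heat shock protein gene Hsph1 (-1.23). Smad6 (-1.19), an inhibitor of BMP signalling, Tsc22d3 (-1.11), a glucocorticoid target, Cables1 (-1.16), Zbtb7c (-1.04), Camk1d (-1.19) and Cmss1 (-1.06) were lower too. Fibroblast-like cells had ratios of the same sign for most of these genes, with Cirbp at 2.11, Hspa5 at -0.91 and Per3 at -2.71, while Smad6 was at 0.03 there.

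Of the 31 lists, 9 lay above and 5 below the random lists. Dissociation stress had the largest median, 1.11, with 16 of 20 members at least 1.5-fold higher and 2 lower, Fos going from 157 to 746 CPM and Atf3 from 24.04 to 201 CPM. It was 1.67 in fibroblast-like cells. Antigen presentation stood at 0.90 with 12 of 15 higher, interferon response at 0.69 with 11 of 16 higher (Ifi27l2a, 9.39 to 59.2 CPM), and glucocorticoid response at 0.42 with 5 of 12 higher and 3 lower (Mt1, 35.9 to 88.1 CPM). Venous and capillary stood at 0.43 with 3 of 10 higher (Nrp2, 2.22 to 5.80 CPM) and the angiogenic front list at 0.31 with 3 of 10 higher and 1 lower. Hox stood at 0.17 with 4 of 22 higher, and oxidative phosphorylation and fatty acid synthesis each at 0.13. Circadian clock genes stood at -0.54 with 7 of 14 lower and 2 higher. Dbp (ENSMUSG00000059824) went from 85.3 to 18.997 CPM, whereas Arntl (ENSMUSG00000055116) went from 5.50 to 27.8 CPM and Npas2 from 5.75 to 33.7 CPM. Imprinted growth genes stood at -0.50 with 8 of 17 lower and 1 higher, S phase at -0.47 with 7 of 20 lower, and matrix at -0.38 with 6 of 21 lower and 1 higher, Eln going from 22263 to 15394 CPM. The 17 other lists had medians between -0.26 and 0.11. Klf2 was 929 CPM at P20 and 1388 at P30, a step at which dissociation stress genes were higher too.

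At this step Xist was 386 CPM at P20 and 150 at P30 in endothelial-like cells, and Ddx3y 8.62 and 40.3. In cells with Y-linked and no Xist UMIs, H2-Q6 was at 1.86, H2-Q7 at 1.39, H2-K1 at 0.80, B2m at 0.53, Iigp1 at -0.37, Nfkbiz at 3.34, Hspa5 at -0.88 and Col4a5 at -1.398, and antigen presentation, at 0.19, no longer stood apart. Imprinted growth genes, dissociation stress, interferon response and circadian clock, 4 of the 14 lists, stood apart under each of 15 alternatives. The mitosis median was -0.21, within the random lists, once mitotic cells were left out, a setting that removes cells by the same genes. Mitosis (-0.98 to -0.21), antigen presentation (0.19 to 0.97) and glucocorticoid response (0.15 to 0.56) stood apart under 14, and S phase (-0.56 to -0.20), matrix (-0.56 to -0.09) and venous and capillary (0.15 to 1.33) under 13. Fatty acid synthesis (0.10 to 0.27) and Hox (-0.15 to 0.24) did so under 12, oxidative phosphorylation (0.12 to 0.24) under 10 and angiogenic front (0.06 to 0.44) under 9. Venous and capillary was at 0.15 without capillary-like clusters, and matrix at -0.11 without cells carrying markers of other classes and at -0.09 in Y-only cells.

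**Figure D2:**
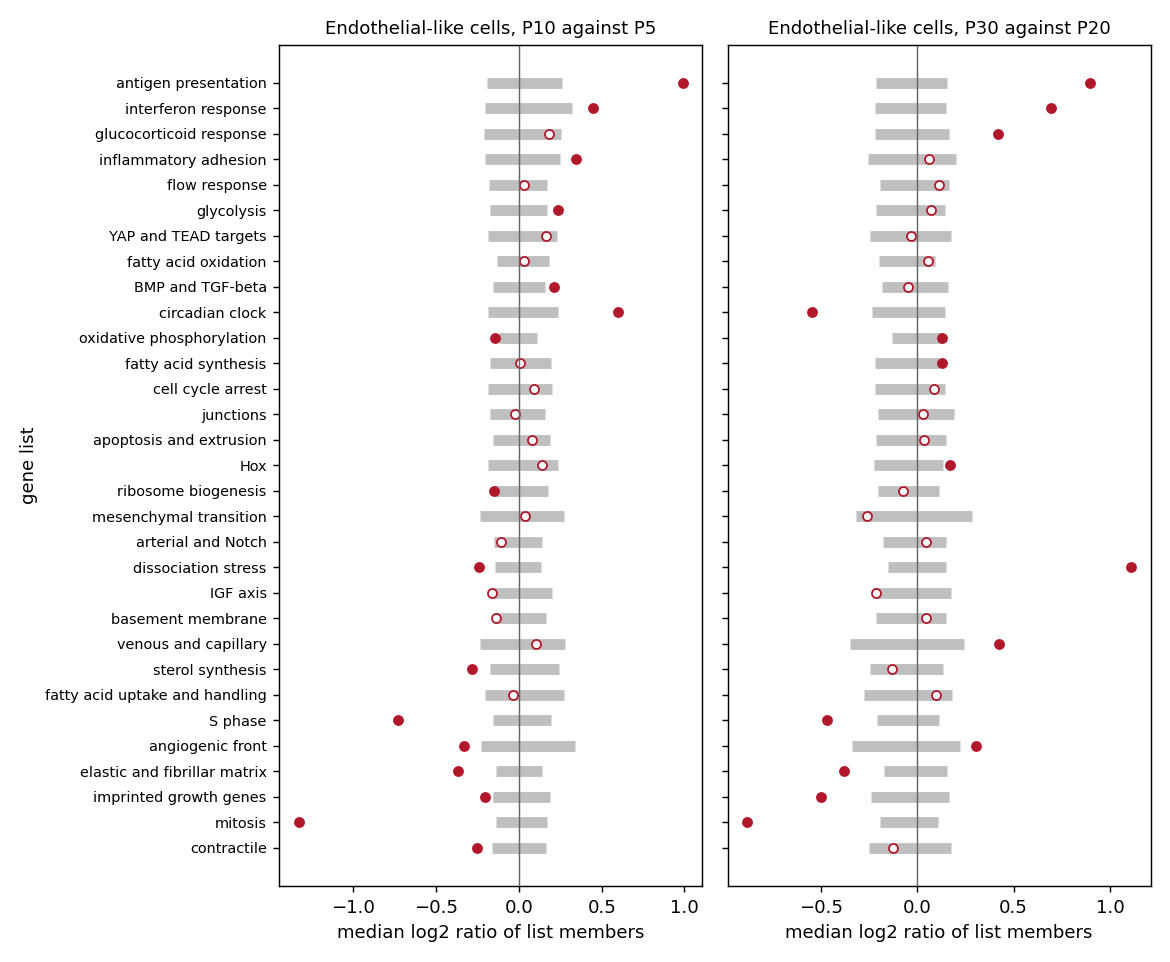
Median log2 ratio (horizontal axis) of each of 31 gene lists (vertical axis) in endothelial-like cells for P10 against P5 and P30 against P20; grey bars are the central 95% of random lists matched on expression, and filled points lie outside them. Mitosis lay at -1.33 and -0.88, antigen presentation at 0.99 and 0.90, and the circadian clock at 0.60 and -0.54.

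Between P10 and P20, where the dissociation also changed, several genes of endothelial-like cells were nearly undetected at P20, and others, such as Apoe and Emcn, were higher. Muc13 was 86.8 CPM at P10 and 0.364 at P20 (log2 -7.90, -8.69 to -7.21), and the Wnt modulator Dkk2 54.9 and 1.54 CPM (-5.16). Myoz3 (-4.96), Nup210l (-4.52), the actin regulator Limk1 (-4.33) and Slco1c1 (-4.11) followed. Apoe, the apolipoprotein, went from 615 to 5230 CPM (3.09, 3.05 to 3.13) and Fam107a, an actin-associated gene, from 4.77 to 57.6 CPM (3.59). Ahsg (2.83), Thbs1 (2.41), a matricellular protein, the solute carrier gene Slc43a3 (2.08) and the sialomucin gene Emcn (2.00) were higher too. With the libraries clustered together Dkk2 was at -3.40, and in Xist-only cells Nup210l was at -2.90 and Slco1c1 at -2.27.

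Lists that stood apart at this step were 8 lower and 6 higher. The lower ones were venous and capillary (-2.08), contractile (-2.02), dissociation stress (-0.99993), angiogenic front (-0.99), imprinted growth genes (-0.72), matrix (-0.70), fatty acid uptake and handling (-0.55) and basement membrane (-0.47). Myh11 went from 105 to 0.791 CPM, Acta2 from 955 to 444 CPM, Fos from 1767 to 157 CPM, Fabp4 from 454 to 122 CPM, Gpihbp1 from 9.54 to 1.28 CPM, H19 from 11.6 to 2.52 CPM and Col1a1 from 971 to 180 CPM. In fibroblast-like cells Col1a1 was 25678 CPM at P10 and 10176 at P20, and H19 125 and 184. Free fibroblast RNA was not subtracted, so the part of these levels that belongs to endothelial-like cells was not measured. The higher ones were glucocorticoid response (0.89), interferon response (0.86), mitosis (0.62), circadian clock (0.56), antigen presentation (0.32) and S phase (0.29). The contractile median was -0.06 after subtraction of smooth muscle RNA at P10. Without mitotic cells mitosis was at -0.71 and S phase at -0.12. That mitosis value is shaped by the selection, which used unthinned UMIs of the same genes at median depths of 4209 at P10 and 5828 at P20. Without clusters rich in capillary genes, which held 44 of the 1545 cells at P10 and most of their Gpihbp1, venous and capillary stood at -0.47 and fatty acid uptake and handling at -0.25, neither outside the random lists. In Xist-only cells, of which P10 had 66, interferon response (0.28), circadian clock (0.0027), S phase (0.38), angiogenic front (-0.55) and fatty acid uptake and handling (-0.61) lay within the random lists and antigen presentation, at -0.51, below them. With doublets kept mitosis was at 1.51. Matrix, basement membrane, imprinted growth genes, dissociation stress and glucocorticoid response stood apart under each of 14 alternatives, and mitosis, venous and capillary, angiogenic front, contractile, interferon response and circadian clock under 13. S phase did so under 12, and fatty acid uptake and handling and antigen presentation under 11.

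From P5 to P30, where the dissociation also changed, genes of antigen presentation, the interferon response and Adh7 were higher in endothelial-like cells. Matrix, imprinted and cell-cycle genes were lower there. Klk10 (ENSMUSG00000030693, chromosome 7, 43781035 to 43785410), a secreted serine protease, was 1.196 CPM at P5 and 88.5 at P30, or 74.0-fold higher (log2 6.21, 5.49 to 7.05). H2-Q6 (5.42), Adh7 (5.05), Apoe (5.04), the keratin gene Krt80 (4.58) and the aldehyde dehydrogenase gene Aldh3a1 (4.11) followed. Sparcl1 (-5.08), Moxd1 (-4.87), a monooxygenase-like gene, Myoz3 (-4.50), the extracellular matrix protein gene Hmcn1 (-4.47), Rtl4 (-4.19) and Nup210l (-3.78) were the lowest. The lists above the random ones were antigen presentation (2.16), interferon response (1.97), glucocorticoid response (1.58), inflammatory adhesion (0.54), flow response (0.35), glycolysis (0.28) and fatty acid oxidation (0.21). Vcam1 went from 52.7 to 351 CPM. Those below were contractile (-2.68), mitosis (-1.65), imprinted growth genes (-1.63), matrix (-1.38), angiogenic front (-1.26), S phase (-1.03), fatty acid uptake and handling (-0.83), sterol synthesis (-0.81), venous and capillary (-0.74), basement membrane (-0.51), IGF axis (-0.48) and dissociation stress (-0.44). Of the 18 imprinted growth genes 15 were lower and 2 higher, and of the 22 matrix genes 19 were lower and 2 higher. Free fibroblast RNA was not subtracted from either list. With the looser cell filter mitosis stood at -0.32, within the random lists, and contractile at 0.40 after subtraction of smooth muscle RNA. Venous and capillary stood at 0.52 without the capillary-like clusters and 0.21 in Y-only cells, and flow response at -0.061 in Y-only cells. Fatty acid uptake and handling stood at -0.52 and -0.41 in these settings, within the random lists. Of the 19 lists, 11 stood apart under each of 14 alternatives, among them interferon response (1.16 to 2.17) and glucocorticoid response (0.68 to 1.78). Mitosis (-1.85 to -0.32), glycolysis (0.22 to 0.49), contractile (-2.71 to 0.40) and the IGF axis (-0.75 to -0.27) stood apart under 13, and fatty acid uptake and handling (-1.07 to -0.41) under 12. Fatty acid oxidation (0.10 to 0.42), flow response (-0.061 to 0.56) and venous and capillary (-1.24 to 0.52) did so under 11. The median over all genes was -0.06 with CPM and 0.10 with TMM factors at P20 against P10, and -0.11 and 0.10 at P30 against P5.

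Genes that differed at least 1.2-fold in the same direction at each of the 3 steps numbered 47 upward and 28 downward among eligible genes. Adh7 stood at 18.6, 78.2, 244 and 614 CPM from P5 to P30, Klk10 at 1.196, 2.68, 46.1 and 88.5, and Atp1b1, a subunit of the sodium pump, at 4.46, 6.40, 39.5 and 53.1. At P5 and P10 Klk10 had only 15 and 23 UMIs and Atp1b1 56 and 55. The Atp1b1 ratio of P10 against P5 (log2 0.52, -0.044 to 1.08) did not leave out equality. Most of both rises lay at P20 against P10 (4.11 for Klk10, 2.63 for Atp1b1), where the dissociation also changed. Clu stood at 304, 470, 718 and 1722 CPM. The other leading upward genes were Aldh3a1 (log2 4.11 from P5 to P30), AW112010 (3.71), Ccdc3 (3.64), Adra2a (3.26), Adh1 (3.08) and Frmd5 (3.07). Downward, Hmcn1 stood at 300, 137, 36.4 and 13.5 CPM, Moxd1 at 134, 61.0, 8.26 and 4.57, and the P-cadherin gene Cdh3 at 61.9, 38.6, 9.05 and 5.60. Rtl4 (-4.19), Rflnb (-3.15), Dync1i1 (-3.02), Rp1 (-3.02), the synaptic adhesion gene Nrxn3 (-2.46), the collagen prolyl hydroxylase gene P4ha3 (-2.42) and Sdk1 (-2.25) completed them. Eln, at 54715, 44128, 22263 and 15394 CPM, and H19, at 33.6, 11.6, 2.52 and 1.37, were lower at each later age. In fibroblast-like cells H19 was 153, 125, 184 and 49.1 CPM, and free fibroblast RNA was not subtracted.

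**Figure D3:**
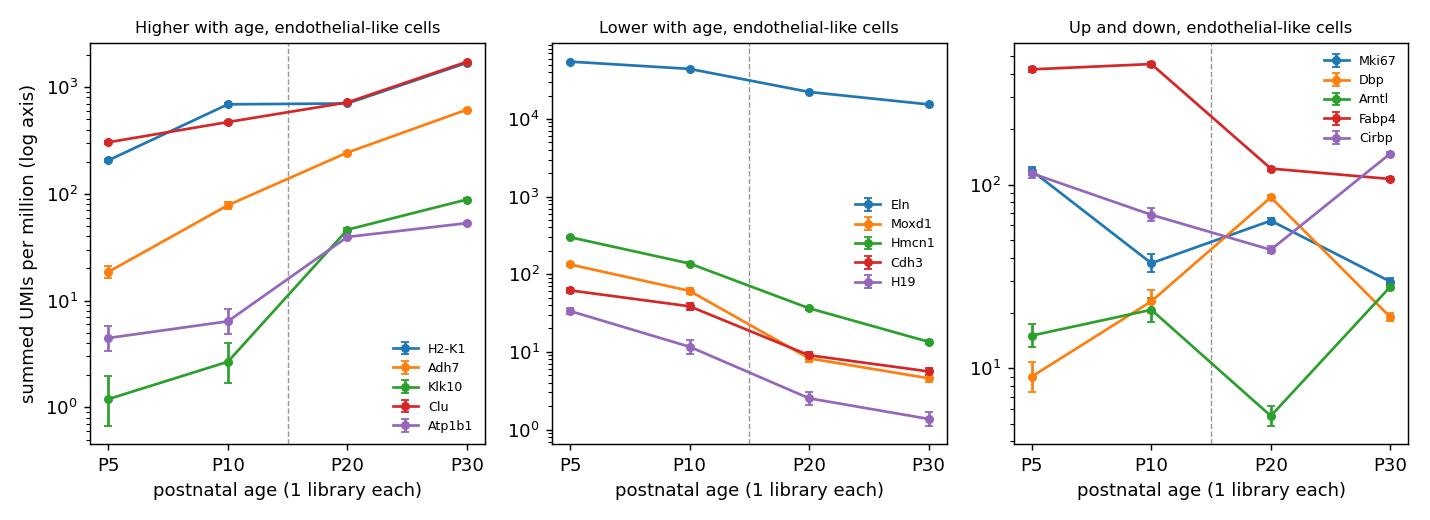
CPM (log axis) of 15 genes in endothelial-like cells by age, in 3 panels, with 95% counting intervals. Adh7 went from 18.6 to 614 and Klk10 from 1.196 to 88.5 CPM between P5 and P30, while Eln went from 54715 to 15394 and Hmcn1 from 300 to 13.5 CPM.

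Smooth muscle-like cells, compared from P5 to P10, also had fewer cell-cycle and more antigen presentation transcripts, and had more Rbp4, Col4a6 and Col4a5 transcripts. Rbp4 (ENSMUSG00000024990, chromosome 19, 38116629 to 38125281), the plasma retinol carrier, was 7.59 CPM at P5 and 154 at P10, or 20.3-fold higher (log2 4.34, 4.23 to 4.46). The collagen IV genes Col4a6 (3.33) and Col4a5 (2.43) and the basement membrane ligand gene Npnt (2.31) were higher. So were Tmcc3 (2.93), Zbtb16 (2.23), a glucocorticoid-induced transcription factor, the semaphorin receptor gene Plxna2 (2.10) and Limk1 (2.07). Lower at P10 were the chemokine gene Cxcl13 (-3.72, -3.86 to -3.59), the collagen prolyl hydroxylase gene P3h2 (-2.32), the N-cadherin gene Cdh2 (-2.23), the phospholipase gene Plb1 (-2.11) and Ccn2 (-2.11), a target of YAP. Gna14 (-1.93), a G protein subunit, Lbh (-1.88) and Tmem108 (-1.85) completed the set. Rbp4 was at 3.05 and Cxcl13 at -5.79 in endothelial-like cells of the same libraries, and at 2.46 and -3.71 in fibroblast-like cells.

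Of the 31 lists in smooth muscle-like cells, 9 lay above and 7 below the random lists. Antigen presentation stood at 1.70 with 13 of 15 members higher, led by class II genes at low levels (Cd74, 1.51 to 15.5 CPM, and H2-Aa, 0.484 to 3.90 CPM). It was 0.63 with the stricter filter, 0.94 in Xist-only and 0.82 in Y-only cells. RNA of other classes was higher in these cells too, Pecam1 standing at 17.1 CPM at P5 and 72.2 at P10, and macrophage-like cells were 0.807% and 1.71% of the kept cells, so the part of this median that belongs to smooth muscle was not measured. Glucocorticoid response stood at 0.92 with 7 of 12 higher (Klf9, 74.5 to 222 CPM), circadian clock at 0.63 with 8 of 14 higher (Dbp, 5.38 to 22.9 CPM), glycolysis at 0.39 (Pfkfb3, 9.59 to 34.2 CPM) and BMP and TGF-beta at 0.35. Cell cycle arrest was at 0.28, dissociation stress at 0.21, matrix at 0.20 and contractile at 0.17. Eln was 46050 CPM at P5 and 61544 at P10, Myh11 1165 and 1530, and Acta2 8155 and 7384. All 22 mitosis genes were lower (-1.04), Cdk1 going from 69.0 to 23.1 CPM, as were 11 of 20 S phase genes (-0.65). Ribosome biogenesis stood at -0.42, YAP and TEAD targets at -0.34 with 6 of 14 lower (Ccn2, 327 to 75.5 CPM), the IGF axis at -0.25 with 5 lower and 5 higher (Igf1, 4.36 to 21.7 CPM), oxidative phosphorylation at -0.25 and imprinted growth genes at -0.22 (Igf2, 22.6 to 9.29 CPM). The 15 other lists had medians between -0.18 and 0.83.

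The median over all genes in smooth muscle-like cells was 0.16 with CPM and -0.02 with TMM factors, under which contractile stood at -0.0067 and matrix at 0.02. Both stayed above the random lists, which TMM factors shift by the same amount. Xist was 542 CPM at P5 and 9.08 at P10 in these cells. With the 151 Xist-only cells of P10, 15 lists lay above and 2 below the random lists, and mitosis stood at -0.06, the IGF axis at 0.43 and Lbh at -0.98. S phase, glycolysis, ribosome biogenesis, antigen presentation, BMP and TGF-beta, circadian clock and glucocorticoid response, 7 of the 16 lists, stood apart under each of 14 alternatives. Mitosis (-1.64 to -0.06), matrix (0.02 to 0.23), imprinted growth genes (-0.40 to -0.20), dissociation stress (0.04 to 0.31) and YAP and TEAD targets (-0.51 to -0.18) did so under 13, the IGF axis (-0.43 to 0.43) under 12, and cell cycle arrest (0.11 to 0.49) and oxidative phosphorylation (-0.43 to -0.09) under 11. The contractile list kept its direction and its side under 9, and lay within the random lists with the looser filter, doublets kept, the mean over cells and mitotic cells left out. In fibroblast-like cells at this step 3 lists lay above and 8 below the random lists, with mitosis at -3.62, antigen presentation at 1.03 and circadian clock at 0.52. At P30 against P20 smooth muscle-like cells were too few to compare, with 14 and 0 cells.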

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

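The tests and the subtraction of smooth muscle RNA in this part were all chosen after the results were seen.

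At P10 against P5, 3 gene lists lay on opposite sides of the random lists in endothelial-like and smooth muscle-like cells, and the difference between the classes was not tested. Elastic and fibrillar matrix had a median log2 ratio of -0.37 in endothelial-like and 0.20 in smooth muscle-like cells, the contractile list -0.25 and 0.17, and dissociation stress -0.24 and 0.21. In smooth muscle-like cells the median over all genes was 0.16, so these positive medians lay close to it.

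Free smooth muscle RNA in the droplets could give such a contrast, because 14 smooth muscle genes outside all lists stood in endothelial-like cells at 16.0% of their smooth muscle-like level at P5 and 7.19% at P10. For the contractile list this stays open: with that share subtracted its endothelial-like median was 0.89, above the random lists, and it stood below them under 6 of 14 alternatives only, while the smooth muscle-like median kept its direction and its side under 9 of 14. Its endothelial-like to smooth muscle-like ratio was 1.17 times that of the 14 genes at P5 and 1.82 times at P10, where free RNA alone needs values near 1, and a value over 2 would have argued against it. For matrix and stress the tables argue against it as the whole cause, since with the share subtracted the matrix median was -0.43 and the stress median -0.31, both still below the random lists. Age, as a biological difference, stays open, and so does the sex mixture for stress, whose endothelial-like median was 0.00036 in Y-only and -0.96 in Xist-only cells, whereas matrix stood below the random lists in both, at -0.29 and -0.45.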

How the results depend on the processing

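Of the alternatives in this part, the Xist-only, Y-only, capillary and smooth muscle RNA settings, hemoglobin-free scaling and added unnamed clusters were chosen after seeing the data. Of 2201 list medians under an alternative, 2020 kept their side of the random lists, of which 119 lay within them and changed sign. Another 105 no longer stood apart, 56 newly did and 20 that stood apart in at least 1 of the settings changed direction. Of 1350 named gene ratios, 934 stayed within their counting interval, 414 moved beyond it and 2 changed direction. Calls that held under every alternative run numbered 5 of 16 at P10 against P5, 5 of 14 at P20 against P10, 4 of 14 at P30 against P20 and 11 of 19 at P30 against P5 in endothelial-like cells, and 7 of 16 in smooth muscle-like cells. TMM factors and hemoglobin-free scaling, which are among these alternatives, could hardly change a call. For the values that follow the cause was not tested.

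Class shares moved with the cell filter, the doublets and the clustering. With the stricter filter smooth muscle-like cells were 63.5% at P5 and 56.8% at P10, and endothelial-like cells 10.0% at P10 and 76.0% at P20. With the looser filter smooth muscle-like cells were 71.3% and 65.4%, and endothelial-like cells 7.21%, 7.47%, 62.7% and 78.3% from P5 to P30. With doublets kept, smooth muscle-like cells were 65.0% and 57.9%, and endothelial-like cells 6.79% at P5, 7.63% at P10 and 75.8% at P30. At resolution 0.5 smooth muscle-like cells were 70.4% at P5 and 56.6% at P10. With the libraries clustered together they were 71.9% and 60.5%, and endothelial-like cells 64.7% at P20 and 76.6% at P30. Fibroblast-like cells at P5 were 9.48% at resolution 0.5 and 10.7% with doublets kept, in place of 14.9%. Smaller classes moved several-fold. Lymphocyte-like cells at P30 numbered 71 with the stricter filter and 99 with doublets kept, in place of 328. Erythroid-like cells numbered 2084 at P20 and 332 at P30 with the looser filter and 1487 and 266 with the libraries clustered together, in place of 400 and 24. Clustering together also gave 90 and 221 macrophage-like cells at P20 and P30 in place of 274 and 398, 341 lymphatic endothelial-like cells at P30 in place of 174, and 47 and 66 lymphocyte-like cells at P5 and P10 in place of none.

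The cycling share of endothelial-like cells from P5 to P30 was 8.60%, 3.04%, 5.29% and 2.03% with thinning to 1000 UMIs, and 21.7%, 6.44%, 7.73% and 3.64% with a minimum of 2 UMIs. It was 6.96% at P5 with the looser filter, 8.43% at P5 and 1.89% at P10 with doublets kept, 2.45% at P30 with the stricter filter and 5.34% at P20 with the libraries clustered together. In smooth muscle-like cells it was 12.5% and 4.73% at P5 and P10 with thinning to 1000 UMIs, 24.6% and 9.08% with a minimum of 2 UMIs, 19.3% at P5 with the stricter filter and 5.95% at P10 with the libraries clustered together.

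Lists that stood apart in endothelial-like cells numbered 10 in place of 16 at P10 against P5 with doublets kept, and 8 in place of 14 at P30 against P20 in Y-only cells. In smooth muscle-like cells 15 lay above and 2 below the random lists in Xist-only cells, in place of 9 and 7. At P10 against P5 the contractile median changed direction, to 0.12 with the looser filter, 0.14 with doublets kept and 0.89 with smooth muscle RNA subtracted. Y-only cells gave -0.36 for flow response, 0.00036 for dissociation stress and -0.25 for interferon response, and Xist-only cells 0.13 for ribosome biogenesis. At P20 against P10, leaving out mitotic cells gave -0.12 for S phase and -0.71 for mitosis, the latter shaped by selecting cells on the same genes. Xist-only cells gave -0.51 for antigen presentation. At P30 against P20, Y-only cells gave 0.37 for contractile, and leaving out cells with other classes' markers -0.15 for Hox. At P30 against P5, flow response was -0.061 in Y-only cells, venous and capillary 0.52 without capillary-like clusters and 0.21 in Y-only cells, and contractile 0.40 with smooth muscle RNA subtracted. In smooth muscle-like cells, Xist-only cells gave 0.43 for the IGF axis and 0.35 for mesenchymal transition, and Y-only cells 0.18 for the IGF axis. TMM factors put the contractile median of smooth muscle-like cells at -0.0067 and left it above the random lists, which they shift by the same amount. Of the named genes, Slco1c1 at P10 against P5 was -0.15 in Xist-only cells and Iigp1 at P30 against P20 was -0.37 in Y-only cells.

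Leaving out cells with other classes' markers was not possible in endothelial-like cells at steps with P5 or P10, since almost every cell carried such a UMI. The 66 Xist-only cells at P10 and 134 Y-only cells at P5 limited the depth of those settings.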

Other observations

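The cluster genes of the first paragraph, the Xist-only and Y-only cells and the Ddx3y check were chosen after the data were seen, while the measures and bounds of the sex mixture and time of day tests were written before their results.

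Large endothelial-like clusters of the scraped libraries differed in Gkn3 and in Nkx2-3, a homeobox gene. At P20, clusters of 1299 and 903 cells held Gkn3 at 1221 and 837 CPM and Nkx2-3 at 11.3 and 9.31, against 424 and 142 CPM in a cluster of 909 cells. At P30, clusters of 1947 and 1828 cells held Gkn3 at 1135 and 1190 CPM and Nkx2-3 at 22.0 and 13.7, against 505 and 130 CPM in a cluster of 2947 cells. At P5 a cluster of 649 cells led by Rflnb, Stmn2 and the muscarinic receptor gene Chrm3 held Nkx2-3 at 14.3 CPM, against 110 CPM in the largest one, and clusters led by Chrm3, Nebl or Stmn2 recurred with 167 cells at P10, 44 unnamed cells at P20 and 198 cells at P30. Small clusters rich in the capillary genes Fabp4, Cd36 and Plvap held 60 cells at P5, 44 at P10, 20 at P20 and 168 and 55 at P30, with Fabp4 at 8308, 10839, 19069, 2921 and 8500 CPM. At P20 and P30 these were low in both genes, with Gkn3 at 49.6, 150.2 and 182 CPM and Nkx2-3 at 9.93, 10.9 and 20.2.

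Cells counted as cycling made up 16.7% of macrophage-like cells at P5, 9.09% at P10, 12.1% at P20 and 1.37% at P30, with 2.63% (2 of 76 cells) at P20 when the libraries were clustered together. In lymphocyte-like cells they were 21.7% at P20 and 31.1% at P30, where 177 of 328 cells were too shallow to count. This order depended on the setting, with 23.1% and 9.86% under the stricter filter, 19.3% and 7.95% with doublets kept, and 14.1% and 12.2% with thinning to 1000 UMIs. In fibroblast-like cells at P30 against P20, 13 lists lay above and 5 below the random lists. Arterial and Notch genes stood at 1.09 there, flow response at 0.58, antigen presentation at 0.92 and S phase at -1.82. Contractile genes separated in endothelial-like cells: at P20 and P30 Acta2 stood at 444 and 417 CPM and Tagln at 440 and 502 CPM, with Myh11 at 0.791 and 0.705 and Cnn1 at 0.791 and 0.508. In fibroblast-like cells of the same libraries Acta2 was 28.3 and 48.2 CPM and Tagln 23.5 and 53.5 CPM. Camk1d, Cmss1 and the ribosomal locus Gm42418 were each highest at P20 in endothelial-like and in fibroblast-like cells, but at P30 Camk1d and Cmss1 were lower than at P10 and Gm42418 was higher. Cmss1 stood at 599, 1920.1, 3366 and 1615 CPM in endothelial-like cells and at 439, 1281, 2057 and 760.2 CPM in fibroblast-like cells.

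Sex mixture differed at both same-dissociation steps. Endothelial-like cells with Xist only and with Y-linked UMIs only numbered 1614 and 134 at P5, 66 and 825 at P10, 4653 and 504 at P20, and 3894 and 3530 at P30, and cells with both 72, 19, 131 and 537. As a check on free RNA, Ddx3y in cells without Xist that held another Y-linked UMI was 82.6 CPM at P5 (57.8 to 114), 82.2 at P10, 66.1 at P20 and 68.9 at P30, against 3.51, 31.9, 1.87 and 13.2 in cells with Xist, so the Xist calls of P10 are the least certain. The tables argue against sex mixture as the whole cause of the named genes as a set. In Y-only cells at P10 against P5 their median ratio was 0.924 times that in all cells. In Xist-only cells at P30 against P20 it was 1.01 times, and all 24 genes kept their direction each time. Resampling the named genes gave ranges of 0.804 to 1.05 and 0.933 to 1.08. These ranges took genes as independent, though many at P10 against P5 belong to the cell cycle. They hold no counting error, such as that of the 134 Y-only cells at P5. For single genes and for the size of the cell-cycle and class I MHC ratios it stays open. In Y-only cells at P10 against P5 Ube2c was at -0.37, Mki67 at -0.96 and Cdk1 at -0.71, nearer 0 than in all cells. The S phase median at -1.19, Adh7 at 3.69 and Adra2a at 3.46 lay farther from 0 there. In Xist-only cells at that step Nusap1 (-3.37), Cenpf (-2.67) and Cks2 (-2.47) lay farther from 0 and Slco1c1 was at -0.15. In Y-only cells at P30 against P20 Iigp1 was at -0.37. H2-Q6 (1.86), H2-Q7 (1.39), H2-K1 (0.80) and B2m (0.53) lay nearer 0 there than in all cells. Antigen presentation, at 0.19, no longer stood apart there. In Xist-only cells at P30 against P20 H2-Q6 (2.88), H2-Q7 (2.25), H2-K1 (1.31) and B2m (1.199) lay slightly farther from 0 than in all cells. Age, as a biological difference, was not tested.

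Clock genes of the P30 against P20 step may reflect libraries collected at different times of day. Dbp (-2.17), Per3 (-1.76) and Hlf (-2.33) were lower and Arntl (2.34) and Npas2 (2.55) higher in endothelial-like cells, and Dbp (-4.25) and Arntl (3.05) were the same way in fibroblast-like cells, as were 12 of 14 clock genes. Of 10 clock genes measured in macrophage-like cells, 5 were, a share of 0.5 (0.187 to 0.813, with genes taken as independent). That is too few genes to decide between a shift of all classes and none. Per3 (-1.18, -2.40 to -0.081), Arntl (0.86, 0.40 to 1.33) and Clock (0.38, 0.025 to 0.74) had counting intervals that left out equality. All of these went the endothelial-like way. The intervals of the others, including the 5 that went the other way, included equality. Time of day and age cannot be told apart here, because each age was collected as 1 library.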
